A study of Mus musculus with 12 samples.

How the data were processed

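The authors' deposited table of counts per gene was used as given, for 12 libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7.11a to GRCm39, and libraries were made from 1 μg of TRIzol-extracted total RNA with the Illumina Stranded mRNA Prep, Ligation kit. The counting tool, its annotation and its strand setting are not given in the sources used here. Groups were taken from the labels. The table names 56441 genes in capital letters, of which 49046 were matched to a mouse spelling by symbol alone with GENCODE M21, which also gave the biotypes. Opposite-strand overlaps of genes came from the same annotation (GRCm38), joined by symbol. Of these genes 28566 had any count and 15228 passed edgeR's filterByExpr (10 counts, 15 in total).

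Counts were modelled with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling) in R 4.3.3, all 12 libraries in 1 model of 4 groups with 8 residual degrees of freedom. The comparisons were FH minus vector in each model, the difference of these 2 effects, and ob/ob minus fasted vector libraries. Adjusted p is Benjamini-Hochberg over the genes tested, called under 0.05. SE is that of the log2 fold change, CPM is on TMM-scaled totals unless library totals are named, and ± is the SD of 3 libraries. Folds against a group with 0 counts are bounds against 3 counts per library, and these bounds cover counting error alone. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry, with p adjusted over the 34 lists that had 4 or more tested members. A list of pancreatic acinar genes had 1 tested member and was not tested. DESeq2 1.42.0 was run beside edgeR. The steps were tested on simulated data with 14953 genes, with 200 changed in each model. In the fasted comparison edgeR called 50% of 2-fold and 81.6% of 4-fold changes, with 7.25% of calls false. In the ob/ob comparison it called 45% and 82.8%, with 3.79% false, and for the difference 26.0% and 71.1%, with 5.45% false. DESeq2 called 67.7% and 83.7% in the fasted comparison, with 16.5% false. The simulated changes were few and balanced in direction. Far more genes differed in the data, so these shares need not hold there and do not test the scaling.

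The groups, comparisons, model, thresholds, gene lists, rule for named genes and the first set of other settings were fixed before the data were examined. Named genes are Fh1 and a fixed panel (Ulk1, Map1lc3b, Sqstm1, Tfeb, Lipa, Pnpla2, Plin2, Cidec, Fasn, Scd1, Srebf1, Cpt1a, Ppara, Fgf21, Cd36, Nqo1, Pck1) in both FH comparisons whatever their p. To these were added, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and no overlap between the libraries compared, and for the difference the 5 largest of each sign. Up to 4 called members of each list with the smallest adjusted p served as examples. Gene models without a name were passed over. The scaling to library totals, the protein-coding subset, the thinning to equal depth, the RNA classes and the genes shown per library (Xist, Y-linked, Malat1, Neat1, Dbp, Arntl, Hsd3b5) were chosen after values were seen. The fit without ob/ob vector replicate 2 was planned and was singled out after values were seen. Also chosen then were the rules and limits by which the tests of sex and of ob/ob vector replicate 2 were decided. Earlier forms of 3 of them gave other answers: a limit of 2 log2 units for Xist left an FH effect open, 2 genes over 4 times all 5 other vector libraries left mixing open, and clock genes alone spoke for another time of day. Nothing states that the libraries of a group came from separate animals, so p-values measure the spread between libraries. Values of some genes that this rule names are not reported.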

Results

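RNA of mouse liver was sequenced in 12 libraries, which the labels place in 4 groups of 3. C57BL/6 mice fasted for 24 h and ob/ob mice on a high-fat diet, which lack functional leptin and become obese, had received an AAV8 vector carrying fumarate hydratase (FH) or the vector alone, at 6 to 8 weeks of age and 1 month before collection. FH turns fumarate into malate in the tricarboxylic acid cycle, and the series asks what more of it does to a fatty liver and to the breakdown of lipid droplets by autophagy. The labels name liver as the tissue and hepatocytes as the cell type, so markers of the other liver cells were measured as well. The libraries held 12231828 to 14884323 counts in the fasted vector group, 19107050 to 25873379 in the fasted FH group, 12573267 to 14496559 in the ob/ob vector group and 21632289 to 23506015 in the ob/ob FH group. Nothing in the labels says that the 3 libraries of a group came from separate mice, so the p-values measure the spread between libraries, which may be technical.

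The delivered gene was higher in the FH libraries of both models. Fh1, the mouse gene of fumarate hydratase, stood at 319 ± 85.5 CPM (SD, n = 3) with the vector and 813 ± 104 CPM with FH in the fasted livers, a 2.55-fold rise (log2 fold change 1.35, SE 0.20, edgeR adjusted p = 9.94e-05). In the ob/ob livers it went from 122 ± 17.9 to 679 ± 106 CPM, a 5.57-fold rise (log2 2.48, SE 0.21, adjusted p = 1.79e-06). The rise was larger in the ob/ob livers by 1.13 log2 units (adjusted p = 0.0267). That difference missed the threshold when any of 5 libraries was left out, with 0.91 (adjusted p = 0.0564) without fasted vector replicate 2, 1.05 (0.0723) without fasted FH replicate 2, 1.11 (0.0558) without fasted FH replicate 3, 1.19 (0.0507) without ob/ob FH replicate 2 and 1.04 (0.0696) without ob/ob FH replicate 3. The sources used here do not give the species of the delivered sequence, so reads of the virus and of the mouse's own gene cannot be separated.

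**Figure D1:**
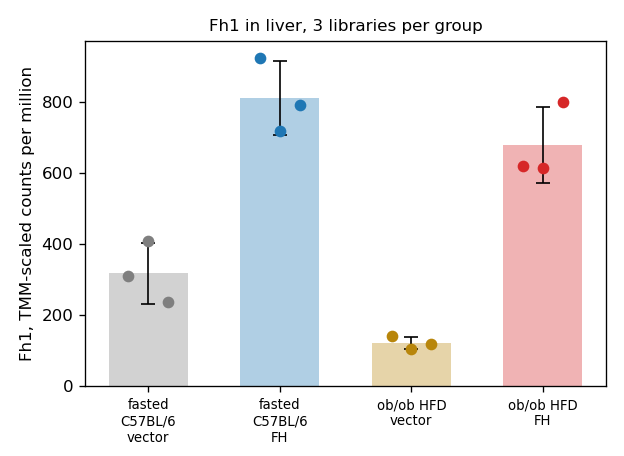
Fh1 in each library, in CPM on TMM-scaled totals (y axis), by group (x axis), with bars for the mean and error bars for the SD of 3 libraries. The fasted groups averaged 319 and 813 CPM and the ob/ob groups 122 and 679 CPM, vector before FH.

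The RNA make-up of the libraries moved with the virus, and this goes with every gene group described for FH. Long noncoding genes took 0.814% to 1.10% of the counts in the fasted vector libraries and 0.263% to 0.306% in the fasted FH libraries, and 0.838% to 0.943% and 0.246% to 0.275% in the ob/ob groups. Malat1, a nuclear noncoding RNA, lay at 472 to 687 CPM in the 6 vector libraries and at 10.5 to 58.4 CPM in the 6 FH libraries, on library totals. Ribosomal protein genes took 2.75% ± 0.801 against 1.52% ± 0.105 in the fasted livers and 2.46% ± 0.674 against 1.22% ± 0.0563 in the ob/ob livers, vector against FH. Thinned to the same 12231828 counts, 20295 to 21345 genes were detected in the vector libraries and 17319 to 18388 in the FH libraries. The TMM factors, which set the median gene near 0, ran from 1.12 to 1.37 with the vector and from 0.721 to 0.907 with FH. Scaling to library totals instead moved the median of all genes by -0.64 in the fasted and by -0.61 in the ob/ob FH comparison and by 0.20 in the vector comparison, in log2 units. Changes are given relative to the TMM scaling.

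The sex-linked genes also moved with a group. The 3 ob/ob FH libraries held 2242 to 4992 counts of Xist, the noncoding RNA of the inactive X, and 0 counts over the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, which allows at most 0.139 CPM on library totals in any of them (3 counts per library). The other 9 libraries held 2304 to 5181 counts of these Y-linked genes and 1 to 24 counts of Xist. On library totals the Y-linked sum was 300 to 352 CPM in fasted vector and 113 to 130 CPM in fasted FH libraries. So the ob/ob FH comparison and the difference between the models hold a difference of sex markers along with FH. The part of either cannot be told apart. Among the ob/ob vector libraries, replicate 2 stood apart from replicates 1 and 3 in clock and sex-biased genes. On library totals Dbp was at 0.564 CPM in it against 48.9 and 48.4 CPM, Arntl at 29.3 against 5.97 and 7.86 CPM, and Hsd3b5 at 448 against 0.0795 and 0 CPM.

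**Figure D2:**
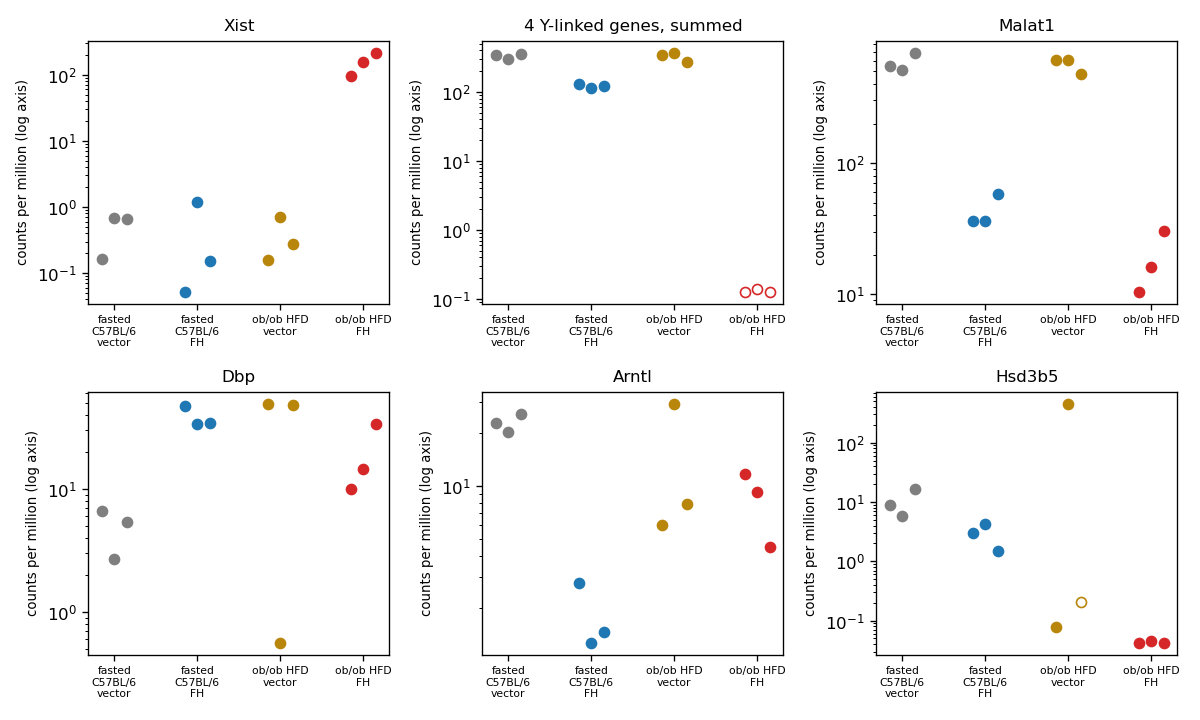
CPM on library totals (y axes, log scale) of Xist, the 4 Y-linked genes summed, Malat1, Dbp, Arntl and Hsd3b5 in each of the 12 libraries, grouped on the x axis; open circles are libraries with 0 counts, drawn at the level of 3 counts. Xist reached 95.6 to 212 CPM in the ob/ob FH libraries, and Malat1 lay at or below 58.4 CPM in the 6 FH libraries.

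In the fasted livers, what FH changed was asked first. Genes of fatty acid oxidation, the cycle around FH and the lysosome rose together with FH, while genes of sinusoidal endothelium fell, and these lists lost their calls with an estimated correlation. Of 37 tested genes of fatty acid oxidation and ketogenesis 32 rose and 1 fell (33 and 1 adjusted over the list alone), among them Hadha (log2 1.87, SE 0.20), Cpt2 (1.53, SE 0.16) and Acadvl (1.37, SE 0.15). Cpt1a, which brings long-chain fatty acids into mitochondria, rose 2.89-fold from 535 ± 124 to 1546 ± 148 CPM (SD, n = 3, adjusted p = 4.50e-04). The list's median was 1.04 (camera adjusted p = 2.10e-07, and adjusted p = 0.457 with an estimated correlation), and on library totals 13 of these genes rose and 3 fell. Of 21 tricarboxylic acid cycle genes other than Fh1, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with Aco1 at 1.56, Mdh2 at 1.51 and Sdha at 1.48, and on library totals 11 rose and 3 fell. The median was 1.04 (camera adjusted p = 4.89e-08, and adjusted p = 0.457 with an estimated correlation). Oxidative phosphorylation had 21 of 34 genes higher and 2 lower (21 and 2 adjusted over the list alone), Ndufa10 at 1.44 among them. Its median of 0.50 turned to -0.17 on library totals, where 8 rose and 12 fell (camera adjusted p = 8.81e-05, and adjusted p = 0.468 with an estimated correlation).

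Most lipid-making genes rose in the fasted livers too, with list calls that were lost with an estimated correlation. Fasn, the fatty acid synthase, went from 23.7 ± 2.63 to 71.4 ± 20.1 CPM (SD, n = 3, 3.02-fold, adjusted p = 1.96e-04), Dgat2 rose by 1.47 (SE 0.12) and Acly by 1.27 (SE 0.16), while Mlxipl, which encodes the carbohydrate-responsive ChREBP, fell by 2.24 (SE 0.27) on the log2 scale. In the lipogenesis list 15 of 22 genes rose and 1 fell (16 and 1 adjusted over the list alone). The median was 1.15 (camera adjusted p = 5.25e-04, and adjusted p = 0.457 with an estimated correlation). In cholesterol synthesis 19 of 23 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 4.53e-05, and adjusted p = 0.457 with an estimated correlation). Srebf1 rose by 0.86 (adjusted p = 0.00659), and Scd1 stood at 0.33 (adjusted p = 0.394), or -0.34 on library totals. Of the lipid droplet genes, Pnpla2, the adipose triglyceride lipase, rose 3.04-fold from 80.5 ± 30.4 to 245 ± 42.9 CPM (n = 3, adjusted p = 7.68e-05), and Cideb (3.05) and Hsd17b11 (2.03) rose more on the log2 scale. The list had 12 of 20 genes higher and 1 lower (13 and 1 adjusted over the list alone), or 7 higher without fasted vector replicate 3, and on library totals 5 higher and 5 lower. The median was 0.92 (camera adjusted p = 0.00733, and adjusted p = 0.510 with an estimated correlation). Plin2 rose by 1.00 (adjusted p = 0.0331), a call lost without fasted vector replicate 2 (1.01, adjusted p = 0.0709), fasted vector replicate 3 (0.84, 0.121), fasted FH replicate 1 (0.90, 0.0902) or fasted FH replicate 3 (0.87, 0.101). Cidec (1.46, adjusted p = 0.114), Cd36 (1.12, adjusted p = 0.128) and Fgf21 (-0.85, adjusted p = 0.305) did not pass the threshold. Ppara rose by 0.75 (adjusted p = 0.0281), a call lost without fasted vector replicate 1 (0.71, adjusted p = 0.0749), 2 (0.77, 0.0594) or 3 (0.75, 0.0721) and without fasted FH replicate 1 (0.57, 0.118) or 2 (0.69, 0.0781), and Pck1 rose by 0.93 (adjusted p = 6.58e-04). Uptake and lipoprotein genes rose in 12 of 19 cases and fell in 2 (13 and 3 adjusted over the list alone), with Mttp at 1.78 and Apoc2 at -2.76. On library totals 5 rose and 4 fell, against 7 and 2 in lipogenesis and 10 and 1 in cholesterol synthesis. The median was 0.87 (camera adjusted p = 0.0121, and adjusted p = 0.457 with an estimated correlation).

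For autophagy, most lysosomal genes rose, though the list lost its call with an estimated correlation. Of 27 lysosomal genes 25 rose and 0 fell (25 and 0 adjusted over the list alone), with Npc1 at 1.55 (SE 0.15) and Ctsd at 1.49 (SE 0.17). Lipa and Tfeb, the lysosomal lipase and a regulator of lysosomal genes, rose by 0.78 and 0.83 (adjusted p = 0.00908 and 0.00718). The median was 0.89 (camera adjusted p = 4.89e-08, and adjusted p = 0.457 with an estimated correlation), and on library totals 10 rose and 2 fell. Ulk1, the kinase that starts autophagy, stood at 68.0 ± 13.3 CPM with the vector and 68.1 ± 7.72 CPM with FH (SD, n = 3, log2 -0.00, SE 0.15, adjusted p = 0.998), and on library totals at -0.68 (adjusted p = 0.0037). Its value ran from -0.21 to 0.11 as single libraries were left out. Of the 14 initiation genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), Pik3r4 at 1.34 and Ambra1 at 0.97 among them. The median of 0.59 became -0.08 on library totals, where 3 rose and 2 fell (camera adjusted p = 0.00171, and adjusted p = 0.457 with an estimated correlation). Of 25 genes of autophagosome formation and cargo receptors 15 rose and 5 fell (16 and 5 adjusted over the list alone), led by Atg7 at 1.61 (SE 0.15). The median of 0.46 became -0.21 on library totals, where 3 rose and 10 fell (camera adjusted p = 0.0283, and adjusted p = 0.457 with an estimated correlation). Sqstm1, the cargo receptor p62, rose 2.05-fold from 374 ± 44.7 to 766 ± 96.0 CPM (n = 3, adjusted p = 1.70e-04). Map1lc3b stood at 0.31 (adjusted p = 0.0529), or -0.36 on library totals, and passed the threshold without fasted FH replicate 2 (0.37, adjusted p = 0.0474).

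In the fasted livers further lists passed by camera, upward or downward, and lost their calls with an estimated correlation. NRF2 targets rose in 16 of 27 cases and fell in 1 (17 and 1 adjusted over the list alone), with Ephx1 at 2.44 and Ces2g at 2.09. The median was 0.95 (camera adjusted p = 6.34e-05, and adjusted p = 0.457 with an estimated correlation), while Nqo1 itself stood at 0.87 (adjusted p = 0.0719). Glycolysis (12 of 16 rose, 2 fell, Slc2a2 at 2.25), the urea cycle and amino acid catabolism (14 of 21 rose, 0 fell, Fah at 1.21), pericentral markers (11 of 14 rose, 0 fell, Cyp2e1 at 1.75) and periportal markers (9 of 13 rose, 0 fell, or 5 without fasted vector replicate 1, Cyp2f2 at 1.89) had medians of 0.96, 0.77, 1.15 and 0.93. Their camera adjusted p were 0.00171, 7.33e-04, 0.00238 and 0.0111, each at adjusted p = 0.457 with an estimated correlation. On library totals NRF2 targets, glycolysis, the urea cycle, pericentral and periportal markers rose in 7, 7, 3, 6 and 4 cases and fell in 2, 4, 1, 3 and 2. Bile acid and sterol transport rose in 7 of 17 genes and fell in 2, Abcg8 at 1.49 (camera adjusted p = 0.0131, and adjusted p = 0.457 with an estimated correlation), with a median of 0.56 that became -0.11 on library totals. All 13 sinusoidal endothelial markers fell, here and on library totals (13 adjusted over the list alone), Stab1 at -2.29 (SE 0.20) and Clec4g at -1.24 (SE 0.12). The median was -0.93 (camera adjusted p = 1.13e-05, and adjusted p = 0.457 with an estimated correlation). Of 16 Kupffer cell and macrophage markers 10 fell and 0 rose, or 6 fell without fasted FH replicate 1, Lyz2 at -1.79 and Clec4f at -1.23. The median was -0.73 (camera adjusted p = 0.0255, and adjusted p = 0.468 with an estimated correlation), a call lost without fasted vector replicate 2 (-0.55, adjusted p = 0.113, 3 falling). Interferon genes fell in 13 of 24 cases and rose in 2, Oas2 at -2.93. The median was -0.67 (camera adjusted p = 0.0283, and adjusted p = 0.468 with an estimated correlation), a call lost without fasted vector replicate 2 (-0.40, adjusted p = 0.136), fasted FH replicate 2 (-0.59, 0.0626) or fasted FH replicate 3 (-0.47, 0.0524). Markers of stellate cells (0 of 15 rose, 3 fell), lymphocytes (0 of 14, 1), cholangiocytes (0 of 6, 0) and adipocytes (3 of 4, 0) had camera adjusted p of 0.171, 0.222, 0.998 and 0.203. On library totals 0 of them rose in any of these lists, and 12, 8, 3 and 0 fell. The stellate list passed without fasted FH replicate 3 (-0.42, 0.0443).

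Clock genes differed between FH and vector in the fasted livers, and the clock list did not pass. That list test asks for a shift in 1 direction, and the members moved both ways, so it cannot exclude a change of the clock. Another time of day of sampling was not tested for the fasted groups, so it cannot be told apart from FH here. Dbp, a clock output gene, rose 12.6-fold from 4.20 ± 1.72 to 52.4 ± 9.48 CPM (SD, n = 3, adjusted p = 0.00358), and Arntl, the clock's activator BMAL1, fell by 2.98 on the log2 scale (SE 0.56, adjusted p = 5.87e-04). Of 17 clock genes 8 rose, Bhlhe41 by 3.08 among them, and 4 fell (median 0.69, camera adjusted p = 0.222, and adjusted p = 0.468 with an estimated correlation). On library totals 3 rose and 4 fell. Among genes with separated groups, which chance gives in 10% of cases, the largest rises included Mir6236 (5.43), Hamp2 (4.80, or 8.17 without fasted vector replicate 3), Cyp2b9 (4.77), Wee1 (3.66), Dbp (3.65), Rgs16 (3.50) and Cyp2a5 (3.19). The call of Cyp2b9 was lost without any single library of the 6 (adjusted p from 0.0523 to 0.0996, log2 4.63 to 4.98). The largest falls were Cd55os, Mroh6, Fendrr, Lilrb4a, Rapgef4os2, Rapgef4os3, Chad and Rgr, from -4.85 to -3.88. Cd55os, Rapgef4os2 and Rapgef4os3 are antisense genes, uncertain because the strand setting of the counting is not given in the sources used here.

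Of 15228 genes tested in the fasted livers, 8382 differed between FH and vector (edgeR, adjusted p under 0.05), 4174 higher and 4208 lower with FH. On library totals 9583 differed, 1087 higher and 8496 lower. At least 2-fold differences were found for 4353 genes, 1415 higher and 2938 lower.

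In the ob/ob livers on the high-fat diet, most genes of the lipogenesis list rose, and the list lost its call with an estimated correlation. For all FH results in these livers, sex markers differed between the groups, so a share of sex cannot be separated from FH. Fasn went from 325 ± 118 to 2086 ± 333 CPM (SD, n = 3, 6.42-fold, adjusted p = 4.64e-06), Acly rose by 2.51 (SE 0.17) and Scd1, the main stearoyl-CoA desaturase of liver, went from 9612 ± 4112 to 34582 ± 10441 CPM (3.60-fold, adjusted p = 3.77e-04). In the lipogenesis list 19 of 22 genes rose and 1, Mlxipl, fell by 1.97 on the log2 scale (20 and 1 adjusted over the list alone). The median was 1.40 (camera adjusted p = 1.17e-07, and adjusted p = 0.265 with an estimated correlation). Srebf1 rose by 1.01 (adjusted p = 0.00151). Cholesterol synthesis rose in 17 of 23 genes and fell in 1 (20 and 1 adjusted over the list alone), with Dhcr7 at 1.98. The median was 0.94 (camera adjusted p = 6.97e-05, and adjusted p = 0.392 with an estimated correlation). Fatty acid oxidation rose in 17 of 37 genes and fell in 1 (15 and 1 adjusted over the list alone), or 11 without ob/ob FH replicate 3, with Hadha at 1.16 and Cpt2 at 1.09. Its median was 0.47, 0.74 without ob/ob vector replicate 3 and -0.14 on library totals (camera adjusted p = 0.00304, and adjusted p = 0.625 with an estimated correlation). Cpt1a rose by 0.81 (adjusted p = 0.0226), a call lost without ob/ob FH replicate 2 (0.79, adjusted p = 0.0582) or replicate 3 (0.75, 0.0679), and by 0.52 without ob/ob vector replicate 2. Pck1 rose by 0.84 (adjusted p = 0.00148), and Cd36 stood at 0.65 (adjusted p = 0.366). Ppara (0.08, adjusted p = 0.821), Fgf21 (0.10, adjusted p = 0.902) and Cidec (0.25, adjusted p = 0.791) did not pass, and on library totals they stood at -0.54, -0.49 and -0.36. The tricarboxylic acid cycle rose in 16 of 21 genes and fell in 1, Cs at 1.40 and Aco1 at 1.34. The median was 0.86 (camera adjusted p = 5.48e-06, and adjusted p = 0.306 with an estimated correlation). Oxidative phosphorylation rose in 17 of 34 genes and fell in 6 (18 and 6 adjusted over the list alone), or fell in 2 without ob/ob vector replicate 1 or ob/ob FH replicate 2 and in 3 without ob/ob FH replicate 3, with Ndufa10 at 1.08. Its median of 0.34 became -0.28 on library totals, and its call (camera adjusted p = 0.0130, and adjusted p = 0.654 with an estimated correlation) was lost without ob/ob FH replicate 1 (0.25, adjusted p = 0.0764). Uptake and lipoprotein genes rose in 8 of 19 cases and fell in 1 (9 and 3 adjusted over the list alone), Mttp at 1.69, with a median of 0.52, or -0.10 on library totals (camera adjusted p = 0.00745, and adjusted p = 0.306 with an estimated correlation). On library totals 13 rose and 1 fell in lipogenesis, 8 and 2 in cholesterol synthesis, 5 and 6 in fatty acid oxidation, 8 and 4 in the tricarboxylic acid cycle, 5 and 18 in oxidative phosphorylation and 4 and 4 in uptake.

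Most lysosomal genes rose in the ob/ob livers too, with a list call lost with an estimated correlation, and the autophagy lists did not pass. Of 27 lysosomal genes 24 rose and 0 fell (24 and 0 adjusted over the list alone), Ctsd at 1.62 (SE 0.17), with Lipa 2.22-fold higher (adjusted p = 7.84e-04), and on library totals 11 rose and 1 fell. The median was 0.89 (camera adjusted p = 1.74e-08, and adjusted p = 0.306 with an estimated correlation). Ulk1 stood at 68.8 ± 2.23 CPM with the vector and 77.3 ± 9.34 CPM with FH (SD, n = 3, log2 0.17, SE 0.15, adjusted p = 0.359), or -0.45 on library totals (adjusted p = 0.0343). Of the initiation genes 6 of 14 rose and 1, Rb1cc1, fell by 1.23 on the log2 scale (SE 0.10). The median was 0.30, or -0.32 on library totals, where 1 rose and 6 fell (camera adjusted p = 0.0935). Of 25 autophagosome and receptor genes 7 rose and 5 fell, with a median of 0.06, or -0.57 on library totals, where 2 rose and 18 fell (camera adjusted p = 0.532). Sqstm1 rose 2.30-fold (adjusted p = 5.54e-05) and Atg7 by 1.17, while Map1lc3b stood at 0.09 (adjusted p = 0.583), or -0.54 on library totals, and Tfeb at 0.37 (adjusted p = 0.175), or -0.25 on library totals. Pnpla2 rose by 0.58 (adjusted p = 0.0464), but stood at -0.04 on library totals, and the call was lost without ob/ob vector replicate 1 (0.60, adjusted p = 0.0837) or 2 (0.45, 0.115) and without ob/ob FH replicate 1 (0.64, 0.0614), 2 (0.56, 0.101) or 3 (0.50, 0.140). The lipid droplet list rose in 9 of 20 genes and fell in 1 (7 and 1 adjusted over the list alone), or 5 rose without ob/ob FH replicate 1, Cideb at 2.76 among them. Its median of 0.59 became -0.04 on library totals, where 2 rose and 3 fell, and its call was lost without ob/ob vector replicate 2 (0.37, adjusted p = 0.175; camera adjusted p = 0.0130 with all, and adjusted p = 0.623 with an estimated correlation). Plin2 stood at 0.78 (adjusted p = 0.0846) and passed without ob/ob vector replicate 3 (1.20, adjusted p = 0.0157).

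The cell cycle, endothelial, macrophage and stellate lists passed upward with FH in the ob/ob livers by camera and lost their calls with an estimated correlation. Lymphocyte, neutrophil, cholangiocyte and erythroid markers did not pass (camera adjusted p = 0.357, 0.513, 0.361 and 0.906), except neutrophil markers without ob/ob FH replicate 1 (1.45, 0.0183). Of 20 cell cycle genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with Mcm5 at 1.99, Ccnd1 at 1.87 and Mcm6 at 1.74. The median was 1.42 (camera adjusted p = 2.08e-05, and adjusted p = 0.265 with an estimated correlation). Sinusoidal endothelial markers rose in 8 of 13 cases and fell in 1 (Pecam1 1.29, Cdh5 1.43), Kupffer cell and macrophage markers in 10 of 16 and 0 (Cd74 2.18, Csf1r 1.80) and stellate and fibrosis markers in 7 of 15 and 1 (Col1a1 1.81, Col1a2 1.65). Their medians were 0.94, 0.98 and 0.83 (camera adjusted p = 0.00348, 9.61e-04 and 0.00496, and adjusted p = 0.405, 0.379 and 0.379 with an estimated correlation), and on library totals 4, 5 and 4 of them rose and 5, 1 and 3 fell. Acute phase and inflammation genes rose in 13 of 20 cases, Itih4 at 2.14. The median was 1.18 (camera adjusted p = 8.98e-04, and adjusted p = 0.265 with an estimated correlation). NRF2 targets (18 of 27 rose, 0 fell, Pgd at 2.26), glycolysis (14 of 16 rose, 1 fell, Gpi1 at 1.73), the urea cycle and amino acid catabolism (17 of 21 rose, 0 fell, Oat at 2.08) and pericentral markers (10 of 14 rose, 0 fell, Cyp2e1 at 1.17) had medians of 1.04, 1.14, 1.22 and 1.24. Their camera adjusted p were 7.02e-06, 2.23e-05, 5.80e-07 and 6.07e-04, and adjusted p = 0.306, 0.306, 0.306 and 0.265 with an estimated correlation. Periportal markers rose in 7 of 13 cases and fell in 0 (8 and 0 adjusted over the list alone), Cyp2f2 at 1.73. The median was 0.86 (camera adjusted p = 0.00341, and adjusted p = 0.379 with an estimated correlation). Nqo1 rose by 1.00 (adjusted p = 0.0376), a call lost without ob/ob FH replicate 1 (1.02, adjusted p = 0.0685) or 3 (0.78, 0.145), and by 0.58 without ob/ob vector replicate 2. Stress response genes rose in 11 of 20 cases and fell in 2, Calr at 1.67 (camera adjusted p = 0.00433, and adjusted p = 0.265 with an estimated correlation), with a median of 0.56, 0.85 without ob/ob vector replicate 3 and -0.06 on library totals. On library totals 10 cell cycle, 9 acute phase, 13 NRF2, 8 glycolysis, 11 urea cycle, 7 pericentral, 4 periportal and 3 stress response genes rose, and 1, 1, 4, 1, 2, 3, 0 and 2 fell.

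The largest changes in the ob/ob livers were in sex-linked and sex-biased genes. The Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d were at least 734-, 494-, 171- and 167-fold lower in the FH libraries, against 3 counts per library, and Xist rose by 9.21 (SE 0.60, adjusted p = 5.54e-07). Of 12 male-biased genes, the 4 Y-linked included, 11 fell and 0 rose. The median was -4.49 (camera adjusted p = 1.17e-19, and adjusted p = 0.265 with an estimated correlation), and it was -1.58 without ob/ob vector replicate 2, with 7 falling. Of 7 female-biased genes 6 rose, A1bg by 7.95 among them. The median was 4.38 (camera adjusted p = 0.0027, and adjusted p = 0.265 with an estimated correlation). Among separated groups, which chance gives in 10% of cases, Sult2a1 was at least 246-fold higher with FH, and Sult2a2, Igkv3-10, Hamp2 and Igkv10-96 were among the largest rises. Sult2a2 had 3 counts in all over the ob/ob vector libraries (mean 0.0543 CPM), under the floor of 3 counts per library, and 122 ± 107 CPM with FH (SD, n = 3). The largest falls besides the Y-linked genes were Slco1a1 (-7.00, or -3.08 without ob/ob vector replicate 2), Muc6 (2.20 ± 1.15 to 0.0157 ± 0.0271 CPM), Meg3 (4.76 ± 5.09 to 0.0469 ± 0.0813 CPM) and Clec2h (-5.63, or -2.99 without ob/ob vector replicate 2). Sult2a, Igkv and Cyp2c genes belong to families of near-identical copies, so their separate values are uncertain.

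Of 15228 genes tested in the ob/ob livers, 8177 differed between FH and vector (edgeR, adjusted p under 0.05), 3932 higher and 4245 lower with FH, and 4095 differed at least 2-fold, 1333 higher and 2762 lower. On library totals 9158 differed, 1039 higher and 8119 lower.

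**Figure D3:**
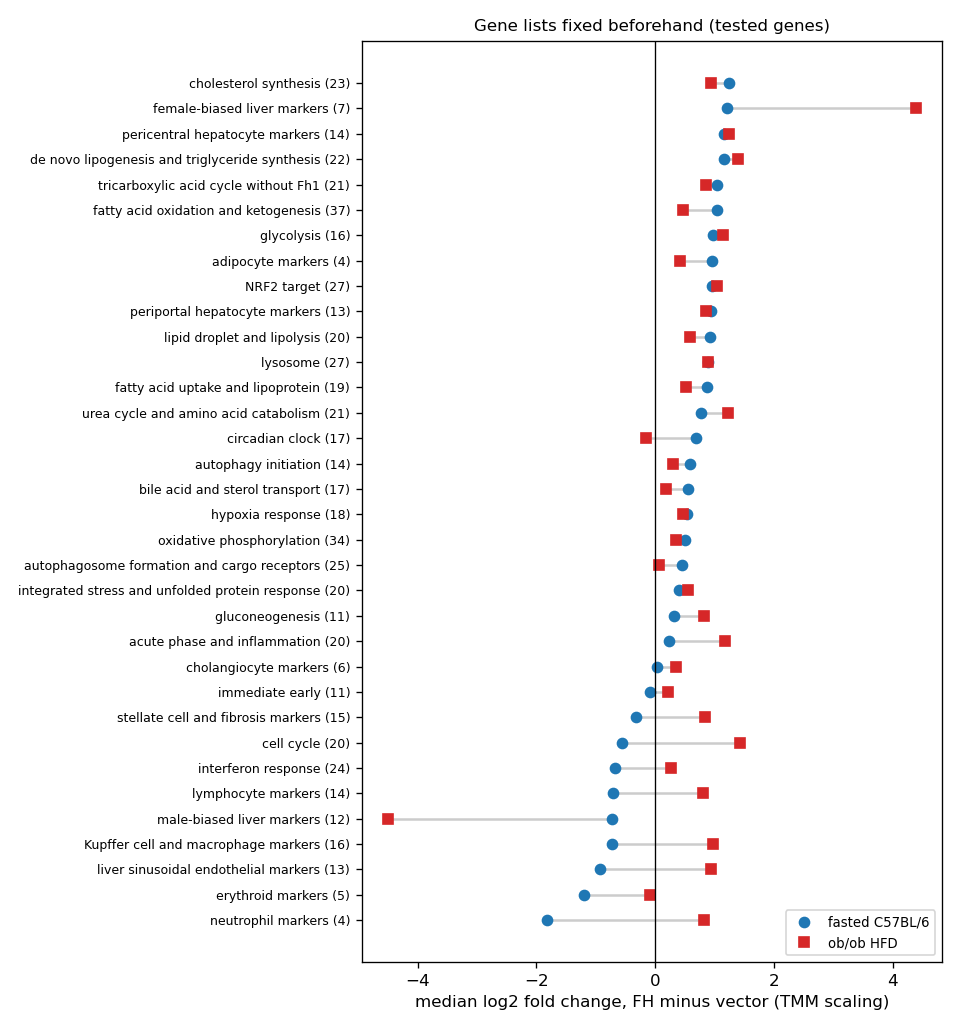
Median log2 fold change of FH against vector (x axis) for the 34 gene lists (y axis, tested genes in brackets), in fasted C57BL/6 (circles) and ob/ob (squares) livers, on TMM scaling. Lysosomal genes lay at 0.89 in both models, and sinusoidal endothelial markers at -0.93 and 0.94; on library totals the medians of autophagy initiation, autophagosome formation, oxidative phosphorylation, hypoxia, bile acid transport, stress response and cholangiocyte lists turned below 0 in both models. Those of gluconeogenesis and acute phase did so in fasted livers alone, and those of lipid droplets, fatty acid oxidation, fatty acid uptake, interferon, immediate early and adipocyte lists in ob/ob livers alone.

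Whether FH acted alike in both models was asked across genes and then gene by gene. Across the 15228 genes, which are not independent replicates, the log2 fold changes of FH correlated with Pearson's r = 0.735 (jackknife SE 0.034 over libraries) and Spearman's rho = 0.720. The genes called in both models in the same direction numbered 2874 higher and 2860 lower, where independent lists would share 1078 and 1173, and 210 were called in opposite directions, where independent lists would give 2250. The FH effect itself differed for 1283 genes (edgeR, adjusted p under 0.05), higher in ob/ob livers for 726 and lower for 557, and 852 of them by at least 2-fold, 665 higher and 187 lower. On library totals it differed for 1083, with 722 higher and 361 lower. The number fell to 778 without fasted vector replicate 3, 706 without fasted FH replicate 2, 800 without ob/ob vector replicate 1, 582 without ob/ob FH replicate 2 and 651 without ob/ob FH replicate 3.

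Endothelial and macrophage markers differed in their FH effect between the models. Xist and the Y-linked genes parted the ob/ob FH from the ob/ob vector libraries, so these differences cannot be separated from sex. The fasted groups both held Y-linked counts and little Xist, but the summed Y-linked level was lower with FH. It was 113 to 130 CPM against 300 to 352 CPM with the vector, on library totals. All 13 sinusoidal endothelial markers had a higher FH effect in ob/ob livers (13 adjusted over the list alone), Pecam1 by 2.00 (adjusted p = 3.11e-04) and Cdh5 by 2.01 (adjusted p = 9.50e-04), with a median of 1.67 (camera adjusted p = 6.67e-32, and adjusted p = 0.0168 with an estimated correlation). So did 11 of 16 Kupffer cell and macrophage markers (13 adjusted over the list alone), Clec4f by 2.18. The median was 1.74 (camera adjusted p = 1.07e-18, and adjusted p = 0.0511 with an estimated correlation). Of 15 stellate and fibrosis markers 8 were higher, or 5 without ob/ob FH replicate 2 (11 adjusted over the list alone), Col1a2 by 1.49. The median was 1.25 (camera adjusted p = 3.52e-10, and adjusted p = 0.0577 with an estimated correlation). Of 20 cell cycle genes 6 were higher (14 adjusted over the list alone), Birc5 by 2.83. The median was 1.68 (camera adjusted p = 5.83e-10, and adjusted p = 0.0511 with an estimated correlation). Male-biased genes had a lower effect in 8 of 12 cases (10 adjusted over the list alone). The median was -5.28, or -2.34 without ob/ob vector replicate 2 (camera adjusted p = 4.59e-58, and adjusted p = 0.0105 with an estimated correlation). Of single metabolic genes, the effect on Acly was higher in ob/ob livers by 1.24 (adjusted p = 0.00641), on G6pdx by 2.46 (0.0011) and on Scd2 by 2.81 (0.00876), and lower on Cyp4a31 (-2.50, 0.0039), Abcg8 (-1.34, 0.00287) and Abcg5 (-1.24, 0.00346). For autophagy, the effect on Rb1cc1, the scaffold of the ULK1 complex, was lower by 1.10 on the log2 scale (-1.10, adjusted p = 0.00151). The differences for Scd1 (1.52, adjusted p = 0.0533), Pnpla2 (-1.03, adjusted p = 0.0646) and Fasn (1.09, adjusted p = 0.0756) missed the threshold. Scd1 passed without ob/ob vector replicate 2 (1.25, adjusted p = 0.0497) or 3 (1.88, 0.0171), Pnpla2 without fasted vector replicate 2 (-1.38, 0.0117) or ob/ob vector replicate 2 (-1.16, 0.0244) and Fasn without ob/ob vector replicate 3 (1.40, 0.0178).

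The vector mice of both models were compared for the setting in which FH was given, and the ob/ob genotype and the diet differ here together with the 24 h fast. The labels give neither a strain background nor a feeding state for the ob/ob mice. Most genes of sterol and fatty acid synthesis were higher in the ob/ob livers and most of amino acid catabolism lower, and of these lists cholesterol synthesis kept its call with an estimated correlation. All but 1 of 23 cholesterol synthesis genes were higher (23 adjusted over the list alone), Fdps 18.0-fold. The median was 2.06 (camera adjusted p = 4.84e-49, and adjusted p = 0.0314 with an estimated correlation). Of 22 lipogenesis genes 14 were higher and 1 lower (16 and 2 adjusted over the list alone), Fasn 13.7-fold and Srebf1 by 3.50 log2 units. The median was 1.51 (camera adjusted p = 3.35e-20, and adjusted p = 0.0512 with an estimated correlation). Of 21 urea cycle and amino acid genes 18 were lower and 0 higher (20 and 0 adjusted over the list alone), Asl at -2.89, Got1 at -2.83 and Arg1 at -1.75. The median was -1.44 (camera adjusted p = 2.05e-25, and adjusted p = 0.0512 with an estimated correlation). Gluconeogenesis was lower in 5 of 11 genes, or 3 without fasted vector replicate 2 or ob/ob vector replicate 3, Pck1 at -1.35. The median was -0.60 (camera adjusted p = 4.60e-05, and adjusted p = 0.0512 with an estimated correlation). Of 20 stress response genes 12 were lower, Creld2 at -1.87 and Hspa5 at -1.24, and 2 higher. The median was -0.64 (camera adjusted p = 9.50e-07, and adjusted p = 0.0423 with an estimated correlation). Fatty acid oxidation had 8 of 37 genes lower and 1 higher, Cyp4a10 at -3.76. Its median of -0.20 was 0.02 on library totals and 0.02 without ob/ob vector replicate 2, and the list's call (camera adjusted p = 0.0020, and adjusted p = 0.785 with an estimated correlation) was lost without that library (adjusted p = 0.408) or fasted vector replicate 1 (-0.07, adjusted p = 0.145). It read -0.30 without fasted vector replicate 3 and -0.39 without ob/ob vector replicate 3. Map1lc3b was lower by 0.84 on the log2 scale (-0.84, adjusted p = 7.12e-04).

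Among the largest differences between the vector groups, without overlap of the libraries, Hao2 was on average at least 67.6-fold higher in the ob/ob livers, with 0.263 CPM in replicate 2 against 0 counts in the fasted vector libraries. Cyp2b13, from the female-biased list, had 41.0, 0 and 50.5 CPM in the ob/ob and 0 in the fasted vector libraries, so these overlapped. Cyp2b9 (10.10), Slc22a29 (7.39), Slc22a27 (6.94), Hcn3 (6.47) and Serpina7 (6.43) were higher as well. In replicate 2 Cyp2b9 stood at 0.788 CPM against 193 and 333 in replicates 1 and 3, Slc22a29 at 0.526 against 25.8 and 21.3, Slc22a27 at 0.946 against 44.3 and 62.2, Serpina7 at 47.0 against 404 and 423 and Cidea at 0.158 against 32.8 and 60.7. Cidea (10.07) went from 0.0222 ± 0.0384 to 31.2 ± 30.3 CPM (SD, n = 3), and Chrna4 stood at 7.60, with few counts in the fasted vector libraries. Fam107a (-5.75), Mup17 (-5.38), Mup15 (-5.28), Ttll8 (-4.17), Scara5 (-3.87, or -6.03 without ob/ob vector replicate 2), Cyp4a10 and Mup16 (-3.53, or -5.55 without that library) were lower, and the Mup genes are near-identical copies whose separate values are uncertain. Of 15228 genes 2671 differed (edgeR, adjusted p under 0.05), 1426 higher and 1245 lower in the ob/ob livers, and on library totals 3378 differed, 2737 higher and 641 lower. The number was 1758 without fasted vector replicate 2, 1669 without fasted vector replicate 3, 1700 without ob/ob vector replicate 1 and 1777 without ob/ob vector replicate 3.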

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

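Tests of sex, of ob/ob vector replicate 2 and of an FH effect shared by both models were chosen only after the result was seen, with the limits that decide those of sex and of this replicate, as was the scaling to library totals. What drew attention to the genes and lists below is a tested difference between the FH effects of the 2 models, and the shared effect and ob/ob vector replicate 2 were taken up from values per library. The difference was called for 1283 genes, and Fh1 itself rose more in the ob/ob livers by 1.13. Of 100 drawn splits, taken from 200, 9 called as many genes, the real one included. The others of these keep the vector and FH groups of 1 model, or both, whole and so carry its FH effect, so this count cannot exclude chance and is no reference without change. The highest other split called 9856 genes, several times the real number, which points to the structure of the samples, since exchanging FH and vector in 1 model adds the effects up instead of subtracting them.

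Sex-linked and sex-biased genes led the difference. Xist was higher in its FH effect in the ob/ob livers by 8.72, Sult1e1 by 5.38, Cyp2c69 by 5.09 and the cell cycle gene Ccnb1 by 4.13, and lower were Ddx3y (-13.35), Eif2s3y (-12.56), Uty (-10.82), Kdm5d (-10.77) and Serpina1e (-8.13). The 4 Y-linked values are fitted to 0 counts in the ob/ob FH libraries and are no measured sizes, and against 3 counts per library the ob/ob falls are bounded at -9.52, -8.95, -7.42 and -7.38. The call of Serpina1e was lost in 10 of 12 fits leaving out 1 library, with -0.36 (adjusted p = 0.750) without ob/ob vector replicate 2, and that of Cyp2c69 in 9 of 12, with 3.22 (adjusted p = 0.120) without ob/ob FH replicate 1 and 7.85 without ob/ob vector replicate 2. Sult1e1 was lost without fasted vector replicate 2 (4.45, adjusted p = 0.0537). Cyp2c and Serpina1 genes are near-identical copies, so their separate values are uncertain.

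Of the gene lists, 18 differed in the FH effect between the models by camera, and 1 list in each direction did so with an estimated correlation. Medians were higher in ob/ob livers for sinusoidal endothelial (1.67), Kupffer cell and macrophage (1.74), stellate and fibrosis (1.25), neutrophil (2.64, camera adjusted p = 4.12e-05, and adjusted p = 0.0637 with an estimated correlation), lymphocyte (1.67, 8.32e-04 and 0.241), erythroid (1.05, 0.0162 and 0.315) and female-biased (5.09, 8.32e-04 and 0.0945) markers, cell cycle (1.68), interferon (0.73, 6.93e-06 and 0.228), acute phase (0.56, 3.17e-04 and 0.0945), urea cycle and amino acid (0.35, 0.0162 and 0.658), lipogenesis (0.26, 0.00656 and 0.558) and stress response (0.17, 0.0249 and 0.270) genes. They were lower for male-biased markers (-5.28), fatty acid oxidation (-0.55, 0.00102 and 0.673), autophagosome formation (-0.36, 0.0258 and 0.323), oxidative phosphorylation (-0.23, 0.0332 and 0.794) and autophagy initiation (-0.22, 0.0332 and 0.517). Without ob/ob vector replicate 2 the lipogenesis list turned to -0.06 (adjusted p = 0.149) and the male-biased list moved to -2.34, and without ob/ob vector replicate 3 lipogenesis read 0.60, acute phase 0.95 and fatty acid oxidation -0.36 (adjusted p = 0.0623). Female-biased markers read 3.03 without fasted vector replicate 2 and 3.22 without ob/ob FH replicate 1, and erythroid markers 0.63 without fasted vector replicate 2.

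The smaller list differences depended on single libraries. Autophagy initiation lost its call without fasted vector replicate 1 (-0.15, adjusted p = 0.164) or 3 (-0.14, 0.0580), fasted FH replicate 1 (-0.22, 0.0610) or 2 (-0.19, 0.0580), ob/ob vector replicate 3 (-0.16, 0.0783) and ob/ob FH replicate 1 (-0.17, 0.0595) or 3 (-0.17, 0.0657), and read -0.38 without fasted vector replicate 2. Autophagosome formation lost it without fasted vector replicate 3 (-0.28, 0.0580), ob/ob vector replicate 3 (-0.29, 0.0723) or ob/ob FH replicate 3 (-0.26, 0.0657), and read -0.23 without fasted vector replicate 1. Oxidative phosphorylation lost it without fasted vector replicate 2 (-0.21, 0.140) or 3 (-0.19, 0.138), fasted FH replicate 1 (-0.20, 0.0665) or 3 (-0.18, 0.0962), ob/ob vector replicate 1 (-0.21, 0.0731) and ob/ob FH replicate 2 (-0.20, 0.112) or 3 (-0.18, 0.126). The stress response lost it without fasted FH replicate 2 (0.08, 0.0626) or 3 (0.07, 0.0655) and ob/ob FH replicate 1 (0.08, 0.0595) or 3 (0.11, 0.0657), and read 0.27 and 0.08 without fasted vector replicates 1 and 3 and 0.29 without ob/ob vector replicate 3. The urea cycle list lost it without fasted vector replicate 2 (0.19, 0.184), ob/ob vector replicate 3 (0.28, 0.135) or ob/ob FH replicate 1 (0.33, 0.107), and read 0.57 without ob/ob vector replicate 1.

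Most FH effects went the same way in both models (77.9% of genes), with Malat1 and Neat1 lower in the 6 FH libraries. Another strand setting of the counting for FH libraries was tested on 569 genes overlapped on the opposite strand by a gene with 10 times their counts. They differed from others of their abundance by -0.19 in the fasted livers (95% interval -0.33 to -0.06) and by -0.60 in the ob/ob livers (-0.76 to -0.45). The fasted value met the limit set beforehand against this cause, which either model could meet. Overlaps of any length were counted, which can draw both values toward 0, so this cause stays open. Another RNA selection stays open. It was tested on 12 RNAs, of histone genes and Rn7sk, taken by name to lack a poly(A) tail, which was not checked in these livers. They had medians of -0.23 (-1.77 to 0.26) and 0.0405 (-0.75 to 0.63) with wide spread. A shared effect of FH stays open as well. The effects on log2 CPM correlated at 0.744, and 1 of 100 pairs of splits, the real one, reached this value (highest other 0.668). The make-up of the libraries is confounded with the virus, however. The 10 splits of 6 libraries are too few for a share under 0.05, with 8382 genes in the fasted (highest other 0), 8177 in the ob/ob (highest other 0) and 2671 in the vector comparison (highest other 1), where 1 split of 10, the real one, called as many in each.

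The ob/ob FH libraries carry Xist and no Y-linked counts, and the ob/ob vector libraries the reverse. An exchange of labels between these groups is argued against, since Fh1 was at least 616 CPM in the ob/ob FH and at most 142 CPM in the ob/ob vector libraries, 0 of which reached the lowest FH library. Female mice in the ob/ob FH group and male mice in the ob/ob vector group would give what was found. The FH libraries held 0 Y-linked and 2242 to 4992 Xist counts, and the vector libraries 4001 to 5181 and 2 to 10. An effect of FH alike in both models is argued against, since Xist moved by 0.49 (SE 0.85) in the fasted against 9.21 (SE 0.60) in the ob/ob livers. Each fasted FH library kept at least 2304 Y-linked counts, though these genes were lower with FH there too, down to a log2 fold change of -1.05. An action in ob/ob livers alone was not tested. By Xist and the Y-linked genes, sex is confounded with FH in the ob/ob livers, and its share of the changes cannot be separated.

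Ob/ob vector replicate 2 stands apart from the other 2 ob/ob vector libraries. An exchange with a fasted vector library is argued against, since 0 fasted vector libraries lay nearer to ob/ob vector replicates 1 and 3. On genes that part these groups, with fasted libraries at 0 and replicates 1 and 3 at 1, replicate 2 lay at 0.50 to 0.58. A fasted library left out of the choice of genes lay at most at 0.20. Another time of day stays open: its clock genes differed from replicates 1 and 3 by a median of 1.36, at percentile 100 of 10000 random lists of the same abundance, but clock genes had drawn attention to this library, and 14 autosomal sex-biased genes differed by 3.23, also at percentile 100. Fasted RNA mixed into it is argued against as the whole cause, on limits set after these values were seen: with 0.4 for the upper limit of 0.25 it would stay open, since 4 genes need more and 5 were asked for, while the best single share left 18 genes outside the range of replicates 1 and 3, with no allowance for other spread. Of 24 genes at least 10 times higher in ob/ob vector replicates 1 and 3 than in every fasted vector library, 10 allow a share of ob/ob RNA under 0.1, such as Cyp2b13 (0 against 41.0 and 50.5 CPM), and 6 need one over 0.25, such as Fasn (219 against 304 and 452 CPM, at most 26.2 in fasted).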

How the results depend on the processing

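The scaling to library totals, the protein-coding subset and the thinning to equal depth were tests chosen after the result was seen. Numbers of called genes are given in the order fasted, ob/ob, difference, vectors. From 8382, 8177, 1283 and 2671 they became 8293, 8146, 1165 and 2689 with DESeq2 size factors, 8774, 8862, 1849 and 3174 without a filter, 8255, 8017, 1303 and 2699 with 10 counts in 3 libraries, 8275, 8145, 1707 and 2994 with DESeq2, 9583, 9158, 1083 and 3378 on library totals, 7764, 7516, 975 and 2526 after thinning, and 6882, 6506, 1254 and 2454 over protein-coding genes. Requiring 2-fold gave 4353, 4095, 852 and 1177, and an adjusted p under 0.01 gave 323 for the difference and 1171 for the vectors, fewer by construction. A replicate block gave 7760, 7673, 707 and 2445, and same-numbered libraries correlated at -0.15 to 0.067, none over 0.1. With the 6 libraries compared alone the vectors gave 1244, with fewer residual degrees of freedom. Leaving out 1 library gave 7214 to 8062 in fasted and 7007 to 8107 in ob/ob livers, 582 to 1650 for the difference and 1669 to 3418 for the vectors, with 1650 and 3418 without ob/ob vector replicate 2, 582 without ob/ob FH replicate 2 and 1669 without fasted vector replicate 3. Fh1 then ran from 1.19 to 1.58 and from 2.32 to 2.61, and the correlation of effects from 0.700, without fasted vector replicate 3, to 0.732. On library totals Fh1 rose by 0.69 (adjusted p = 0.00731) and 1.86. Of 498 named gene results there, 424 stayed called or not called, 63 lost a call and 2 gained one. The 424 include genes uncalled under both scalings whose sign changed, such as Scd1 in the fasted livers. With a call under at least 1 scaling, 9 changed sign: Map1lc3b (-0.36), Atg4b (-0.0537), Xbp1 (-0.16) and Pcna (-0.15) in fasted livers, and Ulk1 (-0.45), Map1lc3b (-0.54), Pnpla2 (-0.0415), Atg4b (-0.0549) and Rab7 (-0.0308) in ob/ob livers, by the shift of all genes that this scaling makes. For the other changes the cause was not tested. Of 136 list results, called or not, 68 lost their call with an estimated correlation. Camera had called 16 lists upward and 3 downward in the fasted livers and 20 and 1 in the ob/ob livers, and 0 of these stayed. For the difference 13 and 5 became 1 and 1, and for the vectors 7 and 8 became 2 and 1.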

Other observations

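The vector libraries of the 2 models differed in further gene groups, which were lists fixed beforehand, and the RNA classes were tests chosen after the result was seen. NRF2 targets were higher in ob/ob livers in 14 of 27 cases, Gstm3 by 4.66, with a median of 0.75 (camera adjusted p = 6.50e-11, and adjusted p = 0.160 with an estimated correlation), and adipocyte markers in 3 of 4, Car3 by 4.21 (median 2.81, or 1.83 without fasted vector replicate 2, adjusted p = 2.47e-05, and adjusted p = 0.0314 with an estimated correlation). Cell cycle genes were higher in 8 of 20 cases and lower in 1, Ccnd1 by 1.73, or higher in 5 without fasted vector replicate 2 or 3 or ob/ob vector replicate 1, with a median of 1.20 (camera adjusted p = 9.60e-06, and adjusted p = 0.159 with an estimated correlation). Glycolysis was higher in 5 of 16 and lower in 1, or higher in 10 without ob/ob vector replicate 2 (median 0.57, or 0.37 without ob/ob vector replicate 3, 0.00105, and adjusted p = 0.516 with an estimated correlation). Periportal markers were lower in 7 of 13 cases, Cps1 at -2.28, with a median of -0.96 (camera adjusted p = 1.03e-06, and adjusted p = 0.170 with an estimated correlation), and sinusoidal endothelial markers in 5 of 13, or 1 without fasted vector replicate 2 or 3 or ob/ob vector replicate 1, with a median of -0.44 (camera adjusted p = 7.24e-04, and adjusted p = 0.498 with an estimated correlation).

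Stellate markers were higher in 4 of 15 cases, Col3a1 by 2.16, with a median of 0.11 (camera adjusted p = 0.0199, and adjusted p = 0.516 with an estimated correlation), with 0.05 and 0.07 without fasted vector replicates 2 and 3, and lost their call without ob/ob vector replicate 2 (0.24, 0.0635). Male-biased markers were lower in 3 of 12 cases, 7 without ob/ob vector replicate 2 and 1 without fasted vector replicate 2 or ob/ob vector replicate 1, Cyp2d9 at -1.61, with a median of -0.31 (camera adjusted p = 0.00513, and adjusted p = 0.516 with an estimated correlation), lost without ob/ob vector replicate 3 (-0.21, 0.0509) and -1.46 without replicate 2. Erythroid markers were lower in 2 of 5 cases, with a median of -0.85 (camera adjusted p = 0.0230, and adjusted p = 0.453 with an estimated correlation), lost without fasted vector replicate 2 (-0.43, 0.0670) or ob/ob vector replicate 2 (-0.51, 0.0635).

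RNA classes moved with FH in both models. Of 1110 tested long noncoding genes 28 rose and 597 fell in the fasted and 16 and 697 in the ob/ob livers (medians -1.30 and -1.62), and of 405 pseudogenes 45 rose and 154 fell, and 35 and 191 (-0.65 and -0.98). Of 12714 protein-coding genes 4007 rose and 3012 fell, and 3784 and 2847 (0.07 and 0.11). This balance depends on the scaling over all genes. Scaled and fitted alone, the protein-coding genes gave 3215 higher and 3667 lower in the fasted and 3095 and 3411 in the ob/ob livers. Albumin took 3.70% to 5.57% of the counts in vector and 7.90% to 11.1% in FH libraries.

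Lists without a call are given by their median and camera adjusted p. In the fasted livers these were hypoxia (0.53, 0.310, or -0.14 on library totals), stress response (0.40, 0.203, or -0.27), gluconeogenesis (0.32, 0.140, or -0.35), acute phase (0.24 with a mean of -0.06, 0.290, or -0.44), cell cycle (-0.55, 0.806), immediate early (-0.08, 0.876), male-biased (-0.72, 0.319), female-biased (1.21, 0.319), neutrophil (-1.81, 0.0570) and erythroid (-1.20, 0.170) genes. In the ob/ob livers they were hypoxia (0.47, 0.361, or -0.16 on library totals), gluconeogenesis (0.82, 0.136), bile acid transport (0.18 with a mean of -0.09, 0.196, or -0.45), interferon (0.27, 0.513, or -0.35), clock (-0.15, against an upward camera statistic, 0.917), immediate early (0.21, 0.532, or -0.40), cholangiocyte (0.35, 0.361, or -0.28), lymphocyte (0.81, 0.357), neutrophil (0.83, 0.513), erythroid (-0.08 with a mean of 0.17, 0.906) and adipocyte (0.42, 0.532, or -0.21) genes. The neutrophil list passed in the fasted livers without fasted FH replicate 1 (-2.52, 0.0433) and in the ob/ob livers without ob/ob FH replicate 1 (1.45, 0.0183). The FH effect did not pass as different between the models for lysosome (-0.04, 0.947, or 0.01 on library totals), lipid droplet (-0.25, 0.681), cholesterol synthesis (-0.11, 0.681), uptake (-0.10, 0.947), tricarboxylic acid cycle (-0.22, 0.209), NRF2 (-0.23, 0.681), bile acid transport (-0.38, 0.0899), clock (-0.62, 0.120), cholangiocyte (0.51, 0.182) and glycolysis (0.00, 0.163) genes. Without ob/ob vector replicate 2 the lipid droplet (-0.49, 0.00505), tricarboxylic acid cycle (-0.30, 0.0201), clock (-0.80, 0.00280) and cholangiocyte (0.41, 0.0461) lists passed, glycolysis passed without ob/ob vector replicate 3 (0.20, 0.0178), and bile acid transport passed without fasted vector replicate 2 (-0.38, 0.0391), fasted FH replicate 1 (-0.41, 0.0230), ob/ob vector replicate 1 (-0.41, 0.0251) or ob/ob FH replicate 1 (-0.34, 0.0489). Clock genes also passed without fasted vector replicate 3 (-0.67, 0.0499). Between the vector groups, autophagy initiation (0.11, 0.479), autophagosome formation (-0.10, 0.132), lysosome (0.08, 0.932), lipid droplet (0.32, 0.312), tricarboxylic acid cycle (-0.06, 0.726) and oxidative phosphorylation (-0.09, 0.609) did not pass, and on library totals autophagosome formation, the tricarboxylic acid cycle and oxidative phosphorylation turned to 0.11, 0.15 and 0.12. Without ob/ob vector replicate 2 the lipid droplet list passed (0.49, 4.18e-06), with 11 genes higher instead of 3, and without fasted vector replicate 3 autophagosome formation did (-0.16, 0.0485). Bile acid transport (-0.23, 0.0679) passed without ob/ob vector replicate 2 (-0.23, 3.26e-04) or fasted vector replicate 3 (-0.32, 0.0431), and female-biased markers (0.38, 0.795) without ob/ob vector replicate 2 (0.84, 0.00266).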
